A study of Arabidopsis thaliana with 15 samples.

How the data were processed

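RNA from whole Arabidopsis thaliana seedlings was measured on Affymetrix ATH1 arrays, which carry 22810 probe sets. The seedlings had grown in light for 5 days on solid medium with sucrose. Wild type (WS2), the brassinosteroid receptor mutant bri1-5, and 3 lines that carry bri1-5 together with a dominant suppressor (bri1-1D, bak1-1D or brs1-1D) were each sampled as 3 biological replicates, 1 array per replicate, which gave 15 arrays. Replicate numbers were taken from the sample titles, because the descriptions of all bak1-1D and brs1-1D arrays give the same number. That the arrays are biological replicates rests on the study's statement for every genotype. Deviations from the genotype means of same-number arrays correlated above 0.1 in all 3 pairs of bri1-5 with WS2, bri1-1D and brs1-1D. In the other 7 of 10 genotype pairs the correlations ran from -0.212 to 0.344. The labels do not say that equal numbers mark a shared batch, and these correlations do not settle it. The main counts and p-values come from a fit without the numbers, and a block by replicate number was run as an alternative.

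The deposited values are log2 expression values per probe set, processed by the authors with GCRMA, which corrects background, normalizes between arrays and summarizes probes. The version and settings of GCRMA are not given in the sources used here. The log2 scale was checked on the values, which ran from 2.01 to 13.5 on the 15 arrays. No counts stand behind array values, so their precision is limited by the number of arrays.

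The platform's gene table listed genes for 14016 probe sets, 13513 with 1 gene and 503 with several. Another 8730 probe sets, apart from 64 array controls, had no listed gene and are given by probe set only. BRI1, BAK1, BRS1 and every member of the fixed lists for brassinosteroid biosynthesis, sterol biosynthesis and seed storage were among the genes without a named probe set, and their levels were not analysed here. Locus codes and gene order came from a RefSeq gene table, and no coordinates were used.

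Probe sets were tested where the log2 value lay above 4 on at least 3 of the 15 arrays. The array controls were left out, which kept 15912 probe sets (8661 with 1 gene). A single linear model with 1 mean per genotype was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend). The 10 pairwise comparisons were read from it, and a probe set was called where the Benjamini-Hochberg adjusted p over all tested probe sets was under 0.05. Changes are log2 differences of group means with the standard error (SE) of the model, n = 3 arrays in each genotype. The p-values measure the spread between the 3 arrays of each genotype, taken as biological replicates.

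Members of 17 gene lists were fixed before the data were examined, together with the comparisons, the alternatives and the rule for naming genes. The lists cover brassinosteroid biosynthesis, sterol biosynthesis, brassinosteroid inactivation, brassinosteroid signalling, brassinosteroid-induced genes, expansins, xyloglucan endotransglucosylase/hydrolases (XTH), auxin response, photosynthesis, salicylic acid defence, pattern-triggered immunity, jasmonate, flavonoid and anthocyanin synthesis, cold and abscisic acid stress, cell cycle, root hair markers and seed storage markers. Of their members 0 of 7, 0 of 8, 1 of 7, 2 of 21, 5 of 23, 9 of 17, 6 of 22, 3 of 25, 7 of 39, 2 of 22, 3 of 15, 3 of 17, 4 of 21, 4 of 22, 1 of 19, 2 of 9 and 0 of 7 were tested, in this order, so each list result covers its tested members only. Each list was tested against the other genes with limma's camera at its preset correlation of 0.01, on 1 probe set per gene, and adjusted over the 9 lists with at least 3 tested members. Camera with an estimated correlation and fry were run as alternatives. Member counts were taken over all tested probe sets and over each list alone.

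The rule for named genes took the 6 largest called rises and the 6 largest called falls among probe sets with 1 gene in bri1-5 against WS2 and in each suppressor against bri1-5. It added up to 4 called members of each list, and the 3 largest rises and falls in every other comparison. Where a probe set had no listed gene, at most a few with the largest changes were named by probe set. Up to 5 tested genes on each side of BRI1, BAK1 and BRS1 were examined in the line named after that locus.

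For each suppressor, probe sets called in bri1-5 against WS2 were counted where they were called with the opposite sign in the suppressor against bri1-5. Both comparisons use the same 3 bri1-5 arrays, so 100 simulations with an unchanged suppressor gave the count and the covariance that shared arrays produce when noise is independent between probe sets. The recovery is the slope, in percent, over all tested probe sets, of the suppressor's change from bri1-5 on the difference of WS2 from bri1-5, after the residual variance of the arrays was taken off the covariance and the variance. The fit was tested on simulated data with noise independent between probe sets, where only bak1-1D held changes and was read against bri1-5. Of 50 probe sets each, 74% were recovered at a simulated log2 change of 0.5, 100% at 1, 98% at 1.5 and 100% at 2. Of the calls, 3.12% were false. The adjusted p depends on how many probe sets change, so these shares do not carry over to the real comparisons.

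Alternatives were another filter or none, quantile normalization, median centring, a floor at log2 4, array weights, a trended and robust variance, a fit of the 6 arrays compared, stricter thresholds, 1 probe set per gene, the replicate number as a block, and leaving out each array. Gene families defined by symbol, tests of clustering along chromosomes, and the count of probe sets changed in all 4 mutant lines were added after the data had been seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures.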

Results

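Gene expression was measured on 15 arrays of whole light-grown 5-day-old Arabidopsis seedlings, 3 biological replicates of each of 5 genotypes. WS2 is the wild type. The bri1-5 mutant carries a weak allele of the brassinosteroid receptor BRI1. The other 3 genotypes are bri1-5 plants with a dominant suppressor named after BRI1 itself (bri1-1D), after its co-receptor kinase BAK1 (bak1-1D) or after the serine carboxypeptidase-like gene BRS1 (brs1-1D), and they are called by the suppressor's name below. Median log2 values over tested probe sets ran from 6.75 to 6.82 between arrays. Correlations between arrays across genes were 0.99 to 0.995 within genotypes and 0.976 to 0.993 between genotypes, where genes are not independent replicates. The first principal component held 32.6% of the variance and set WS2 (-26.06 to -21.48) apart from bri1-5, bri1-1D and brs1-1D (6.55 to 13.85), with bak1-1D at -10.31 to -6.37.

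**Figure D1:**
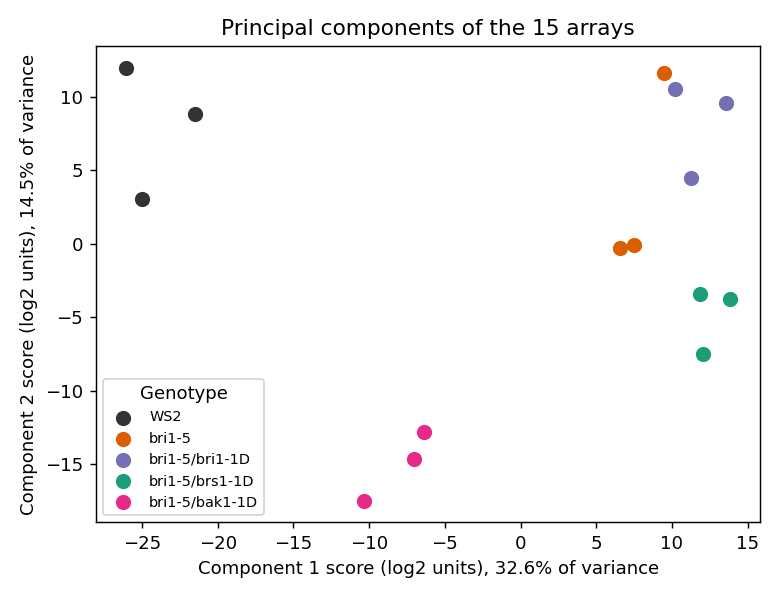
Scores of the 15 arrays on the first component (horizontal, log2 units, 32.6% of the variance) and the second (vertical, log2 units, 14.5%), 1 point per array, coloured by genotype. The 3 bak1-1D arrays lie between WS2 and the other mutant arrays on the first component, and lowest of all arrays on the second.

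The first question was what the weak receptor allele changes in the seedling. Genes known to be induced by brassinosteroid fell in bri1-5 against WS2. EXO, which codes for an extracellular protein that promotes growth, fell by 2.26 ± 0.18 on the log2 scale (SE, n = 3 against 3, adjusted p = 8.59e-07). The expansin EXPA8 fell by 1.95 ± 0.18, the cell wall enzyme XTH19 by 1.29 ± 0.14, the tubulin TUB1 by 0.97 ± 0.11 and ARL, an ARGOS-like regulator of organ size, by 0.49 ± 0.10. For EXO, EXPA8 and XTH19 every bri1-5 array lay more than 1 log2 unit below every WS2 array.

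All 5 tested of the 23 members of the brassinosteroid-induced list were called lower over all probe sets and also when adjusted over the list alone, and the list as a whole fell (median -1.29, camera adjusted p = 1.35e-09). Of 6 tested XTH genes, whose products remodel cell wall xyloglucan, XTH16 (-1.42), XTH19, XTH18 (-0.95) and XTH33 (-0.72) fell and 2 were not called. That list fell too, with 4 members lower when adjusted over the list alone (camera adjusted p = 4.03e-05). The 9 tested expansins did not move together. EXPA8 and EXPB1 (-0.52) fell and EXPA15 rose by 0.57, or 2 higher and 2 lower when adjusted over the list alone. Their median was 0.10, their mean -0.18 and the camera direction down, with an adjusted p of 0.67.

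Cold-regulated genes rose in bri1-5. COR15A, which protects chloroplasts in the cold, rose by 1.94 ± 0.28, and COR15B by 1.00 ± 0.29, a call lost without WS2 replicate 1, WS2 replicate 2 or bri1-5 replicate 1 (adjusted p up to 0.0995). They were 2 of 4 tested members, or 3 when adjusted over the list alone, and the list rose (adjusted p = 0.013), although not beyond its members' own correlation (adjusted p = 0.451 with an estimated correlation). Without bri1-5 replicate 1 the list's adjusted p was 0.0582 at the preset correlation. Single members of other lists moved without a call for the list. The auxin-conjugating enzymes GH3.3 (-0.86) and WES1 (0.89) went opposite ways, the immune receptor EFR rose by 0.85 while WRKY22 fell by 0.75, THI2.1 of the jasmonate list fell by 0.94, and UGT78D2 of the flavonoid list rose by 0.35 (adjusted p = 0.053 without WS2 replicate 1). Adjusted p for the auxin, immunity, jasmonate, flavonoid and photosynthesis lists ran from 0.106 to 0.927, and 0 of 7 photosynthesis genes were called by limma, with 1 at an unadjusted p under 0.05. When adjusted over the list alone, the counts of these 5 lists did not differ from those over all probe sets.

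Among lists with too few tested members for a test, the mitotic kinase gene AUR1 fell by 0.48. BRL1 (0.32 ± 0.12) and BIM1 (0.27 ± 0.11) of brassinosteroid signalling, BAT1 of inactivation (-0.11 ± 0.10), SAG101 and WRKY53 of salicylic acid defence (0.30 ± 0.11 and 0.11 ± 0.22) and the root hair markers EXPA7 (-0.36 ± 0.16) and EXPA18 (-0.35 ± 0.14) were not called over all probe sets. When adjusted over the list alone, both signalling genes and SAG101 were higher, both root hair markers lower, and BAT1 was not called. The lists for brassinosteroid biosynthesis, sterol biosynthesis and seed storage had 0 tested members. Among all probe sets with 1 gene, list members included, the largest rises were those of COR15A, AT5G01740 (1.92 ± 0.13), AT1G72060 (1.79), AT2G07240 (1.67), AT5G53710 (1.65) and AT1G20070 (1.33). The largest falls were those of AT1G14210 (-2.83 ± 0.12, adjusted p = 4.65e-10), EXO, the calmodulin-like gene CML38 (-2.02), EXPA8, APL4, a subunit of the starch enzyme ADP-glucose pyrophosphorylase (-1.84), and AT4G27280 (-1.80). Of probe sets with no listed gene, 245501_at was higher by 3.56 ± 0.10 and 260856_at lower (-2.55 ± 0.19).

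In total 2799 of 15912 probe sets were called, 1503 higher and 1296 lower, and 150 of them changed at least 2-fold (57 higher, 93 lower). The split depended on scaling, with 1152 higher and 1605 lower after median centring, while the median over all probe sets stayed within 0.1 of 0. Without bri1-5 replicate 3 the count was 1761. The 25S rRNA control probe set, which is not part of the tested set, stood at 7.01 to 7.68 on the bri1-5 arrays and 6.10 to 6.27 in WS2 (1.07 ± 0.28, adjusted p = 0.111 over the controls).

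**Figure D2:**
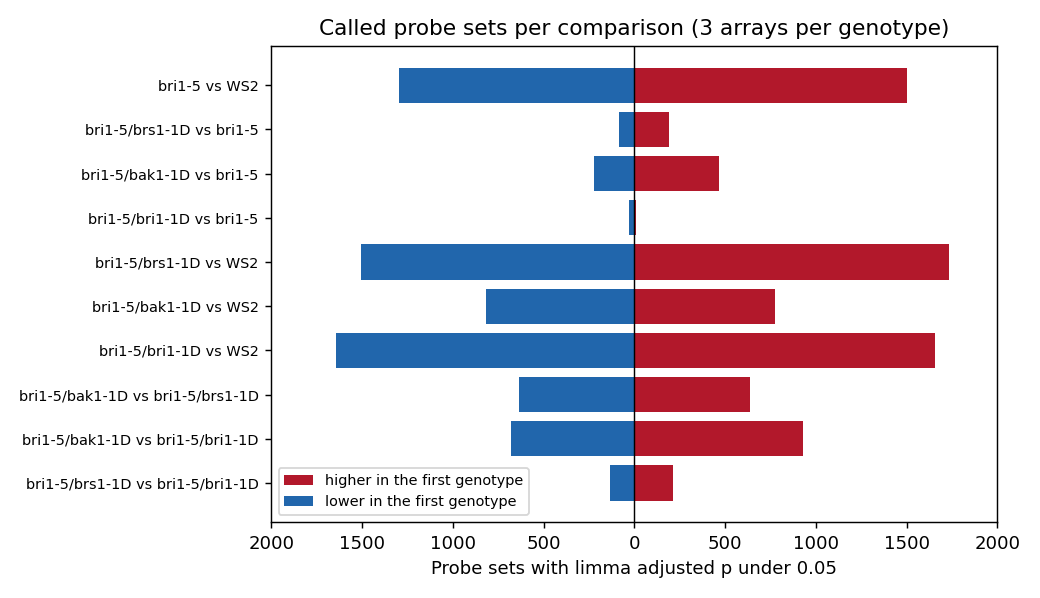
Number of probe sets called by limma at an adjusted p under 0.05 (horizontal axis) in each of the 10 comparisons, higher in the genotype named first to the right and lower to the left, with 3 arrays per genotype. Comparisons with WS2 gave from 1595 to 3300 calls, and suppressors against bri1-5 from 39 to 690.

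The next question was what each suppressor changes in the mutant. In bak1-1D several genes that were low in bri1-5 rose. EXO rose by 1.64 ± 0.18 (adjusted p = 1.86e-04), EXPA8 by 1.10 ± 0.18, XTH18 by 0.75 ± 0.14, XTH19 by 0.52 ± 0.14 and TUB1 by 0.41 ± 0.11. The calmodulin-like gene CML38 rose by 1.42, and the transcription factor genes WRKY22 and WRKY53 by 1.03 and 0.82. The largest other rises were those of AT3G55840 (1.65 ± 0.29), AT2G20670 (1.52), AT4G24380 (1.32) and AT5G05300 (1.29). The largest falls were those of AT4G33720 (-1.65 ± 0.19), AT4G34950 (-1.24), the defensin gene PDF1.4 (-0.90), AT4G27900 (-0.86), AT3G51400 (-0.82) and AT5G14230 (-0.82).

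Of the 5 tested brassinosteroid-induced genes, 4 rose in bak1-1D, over all probe sets and also when adjusted over the list alone, and the list rose (median 0.52, camera adjusted p = 1.16e-06). ARL was not called (0.04 ± 0.10). Among expansins, EXPA8 and EXLA2 (0.64) rose while EXPA16 (-0.63) and EXPA9 (-0.35) fell, or 4 higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.0596). The expansin list was called without the filter on low values (adjusted p = 0.0347), but not by fry (0.207) or with an estimated correlation (0.243). XTH18 and XTH19 were the 2 called XTH genes, also when adjusted over the list alone (camera adjusted p = 0.0507). The XTH list was called with the replicate block (adjusted p = 0.0292), without the filter on low values (0.0347) and by fry (0.0129). With an estimated correlation it was not called (0.104). The 3 tested auxin response genes rose as a list (adjusted p = 0.0148, and adjusted p = 0.078 with an estimated correlation), with GH3.3 called on both scales of adjustment (0.35). The call of the auxin list was also lost without bak1-1D replicate 2 (adjusted p = 0.0512). The pattern-triggered immunity list, with WRKY22 its 1 member called either way, had an adjusted p of 0.0507. That list was called with the replicate block (0.04), without the filter on low values (0.0347) and by fry (0.0337), but not with an estimated correlation (0.13). The photosynthesis, jasmonate, flavonoid and cold lists had adjusted p from 0.0604 to 0.509 and 0 members called by limma, also when adjusted over the list alone, with 1 flavonoid member at an unadjusted p under 0.05.

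In all, 690 probe sets were called in bak1-1D against bri1-5, 468 higher and 222 lower, and of the 74 changed at least 2-fold 72 were higher. After median centring 583 were higher and 157 lower. Without bak1-1D replicate 2 the count was 321 and without bri1-5 replicate 2 it was 322, and with array weights it was 1256. Of 23 named calls 16 held whichever array was left out, while those of TUB1 and XTH19 ended without any 1 of 10 and 9 arrays (adjusted p up to 0.151 and 0.17), and those of WRKY53, EXPA9, EXLA2, GH3.3 and PDF1.4 in at least 3 such fits each.

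In brs1-1D against bri1-5, AT1G10585 rose by 1.57 ± 0.32 (adjusted p = 0.0189), AT4G28140 by 1.32 ± 0.27, AT1G47400 by 1.23, the glycosyltransferase gene UGT76E12 by 1.21, AT5G53710 by 1.14 and the lectin gene JAL23 by 1.14. DFR, which codes for a late enzyme of anthocyanin synthesis, rose by 0.86 ± 0.17. The largest falls were those of AT4G30620 (-1.21 ± 0.14, adjusted p = 6.89e-04), AT3G10040, listed also as HRA1 (-1.08), AT3G23880 (-0.95), AT1G33055 (-0.93), AT4G28703 (-0.92) and AT3G19850 (-0.83). A probe set with no listed gene, 253579_at, rose by 5.32 ± 0.08 to 11.1, the largest change in this comparison, and 247406_at fell by 0.85 ± 0.11.

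The tested brassinosteroid-induced genes gave no call of a rise by limma in brs1-1D. EXO (-0.46 ± 0.18), EXPA8 (0.17 ± 0.18), XTH19 (-0.23 ± 0.14) and TUB1 (0.10 ± 0.11) were not called, and ARL fell further (-0.54 ± 0.10), the 1 member called also when adjusted over the list alone. The list's camera adjusted p was 0.143. Fry called this list (median -0.23) and the XTH list (median -0.18), with an adjusted p of 0.0492 for each, and camera called neither. Of 4 flavonoid genes DFR was called, 2 were higher when adjusted over the list alone, and the list rose (adjusted p = 0.0154, and adjusted p = 0.0878 with an estimated correlation). That call was lost without brs1-1D replicate 2 (adjusted p = 0.0885). The cold list rose with 0 of 4 members called by limma, 1 when adjusted over the list alone and 2 at an unadjusted p under 0.05. Its adjusted p was 0.0458, and adjusted p = 0.347 with an estimated correlation. It missed the threshold without 1 of 9 arrays: bri1-5 replicates 2 and 3 (0.596 and 0.061), brs1-1D replicates 1 and 3 (0.0817 and 0.183), bak1-1D replicates 1 to 3 (0.0504, 0.0508 and 0.0527), bri1-1D replicate 1 (0.0579) and WS2 replicate 1 (0.0531). It also missed it with the replicate block (0.0686), a floor (0.0543), fry (0.265) and median centring. The remaining 6 lists had adjusted p from 0.0798 to 0.933 and 0 called members by limma, with 2 auxin, 2 jasmonate and 1 expansin gene at an unadjusted p under 0.05. When adjusted over the list alone, auxin response had 1 member higher and 1 lower, jasmonate 1 higher, and XTH, expansins, photosynthesis and immunity 0. The root hair marker EXPA7 stood 0.63 ± 0.16 higher (adjusted p = 0.0517), and 0.53 ± 0.16 higher in bak1-1D (adjusted p = 0.0688). It was called in both lines, with EXPA18 (0.33 and 0.35), when adjusted over the list alone. Of the signalling genes, BIM1 and BRL1 were not called over all probe sets (0.27 ± 0.11 and 0.12 ± 0.12 in brs1-1D, -0.24 ± 0.11 and -0.29 ± 0.12 in bak1-1D). When adjusted over the list alone, 1 was higher in brs1-1D and both were lower in bak1-1D.

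The brs1-1D count was 273, with 188 higher and 85 lower and 31 changed at least 2-fold. It fell to 112, 132, 139 and 170 without brs1-1D replicate 2, bri1-5 replicate 3, brs1-1D replicate 3 and bri1-5 replicate 1, and it was 457 with array weights and 410 with the replicate block. With the block AT1G47400 and JAL23 were not called (adjusted p = 0.053 for each). Only AT4G30620, AT1G33055 and AT4G28703 of 15 named calls held whichever array was left out.

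In bri1-1D against bri1-5 few genes differed. AT2G22200 rose by 0.73 ± 0.13 (adjusted p = 0.0357), AT3G16560 by 0.52, AT2G41190 by 0.50 and EXPA16 by 0.44, and no other probe set with 1 gene was called higher. The largest falls were those of AT4G19430 (-0.88 ± 0.13), AT4G19530 (-0.87), AT5G57760 (-0.77), AT1G35350 (-0.76 ± 0.10, adjusted p = 0.002), AT2G34510 (-0.67) and AT5G24210 (-0.67). ARL fell by 0.65 ± 0.10 and GH3.3 by 0.46 ± 0.09. EXO (-0.32 ± 0.18) and EXPA8 (0.59 ± 0.18) were not called. Of probe sets with no listed gene, 252891_at rose by 0.92 ± 0.10 and 251785_at fell by 1.31 ± 0.10. The 25S rRNA control probe set stood at 7.94 to 8.50 in bri1-1D and 7.01 to 7.68 in bri1-5 (0.91 ± 0.28, adjusted p = 0.336 over the controls).

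The 3 tested of 25 auxin response genes fell as a list in bri1-1D (median -0.46, camera adjusted p = 4.09e-05), with 1 called and 3 lower when adjusted over the list alone. Tested without the filter on low values, which adds members, the list had an adjusted p of 0.0556. Of the 5 tested brassinosteroid-induced genes, 1 was lower, and 1 higher and 1 lower when adjusted over the list alone (adjusted p = 0.793). Expansins had 1 called member, or 2 higher and 1 lower when adjusted over the list alone, with median and mean both -0.03, the camera direction up and an adjusted p of 0.793. XTH and photosynthesis had 0 called by limma, 2 and 1 lower when adjusted over the list alone, and 3 and 2 at an unadjusted p under 0.05. The immunity, jasmonate, flavonoid and cold lists had 0 on both scales of adjustment, with 1 immunity gene at an unadjusted p under 0.05. Adjusted p of these 6 lists ran from 0.0889 to 0.985.

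The bri1-1D count was 39, with 11 higher and 28 lower and 3 at least 2-fold lower. It was 6 without bri1-5 replicate 3, 16 without bri1-1D replicate 3, 19 without bri1-5 replicate 1, 6 in a fit of the 6 arrays alone and 61 with array weights. Of 13 named calls, AT1G35350 held whichever array was left out. With the replicate block AT3G16560, EXPA16, AT5G57760, AT2G34510 and GH3.3 were not called (adjusted p from 0.0505 to 0.0585).

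**Figure D3:**
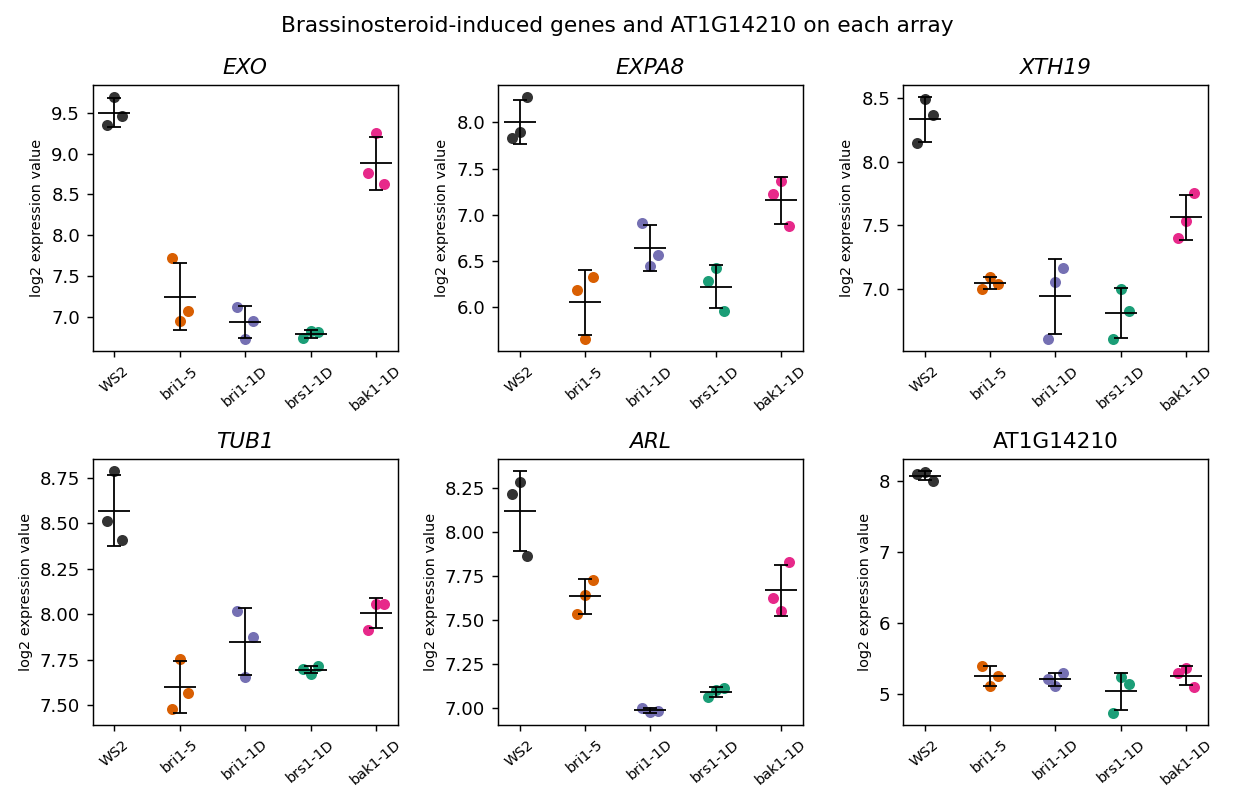
Log2 expression values (vertical axes) of 5 brassinosteroid-induced genes and AT1G14210 on each array, 1 point per array, with the mean and SD of the 3 arrays of each genotype. EXO stands at 9.35 to 9.69 in WS2, 6.94 to 7.72 in bri1-5 and 8.63 to 9.25 in bak1-1D, while AT1G14210 stays at 4.74 to 5.39 in all 4 mutant lines.

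How far each suppressor moves the mutant's changes back toward wild type was asked of the 2799 probe sets called in bri1-5. In bak1-1D, 401 of them were called in the opposite direction, 297 that were low in bri1-5 and 104 that were high, and 13 in the same direction. EXO, EXPA8, XTH18, XTH19, TUB1, CML38, WRKY22 and GH3.3 were among those low in bri1-5 and raised in bak1-1D. Other genes did not follow, such as AT1G14210 (0.00 ± 0.12), APL4 (-0.06 ± 0.10) and XTH16 (-0.02 ± 0.14). In brs1-1D 80 were opposite (55 low and 25 high in bri1-5) and 32 the same. In bri1-1D 15 were opposite (2 and 13) and 8 the same.

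The opposite counts expected of independent lists were 59.1 for bak1-1D, 23.3 for brs1-1D and 3.5 for bri1-1D, and simulations of the shared bri1-5 arrays with an unchanged suppressor gave at most 1, 1 and 2, since an unchanged suppressor has few calls by construction. The covariance of the changes was -0.0344 in bak1-1D against a simulated -0.00752, and -0.0101 in brs1-1D against -0.00747. In bri1-1D it was -0.00706 against a simulated -0.00751, a range that reached from -0.00842 to -0.00621. The recovery was 40.8% in bak1-1D (35.3 to 44.1 with 1 array left out), 3.92% in brs1-1D (0.27 to 8.72) and -0.64% in bri1-1D (-4.37 to 4.70). The simulations and the recovery leave out any pairing by replicate number, and the simulations also leave out deviations shared by many genes on an array. Part of any excess may come from the shared bri1-5 arrays, because 3 arrays cannot be divided into 2 sets that both hold replicates.

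The count of opposite calls in bak1-1D was 204 without bri1-5 replicate 2, 220 without bak1-1D replicate 2 and 699 with array weights. In brs1-1D it was 31 and 35 without brs1-1D replicates 2 and 3, 36 and 39 without bri1-5 replicates 1 and 3, 49 without WS2 replicate 3, 148 with array weights and 128 with the replicate block. In bri1-1D it was 3 and 6 without bri1-5 replicates 3 and 1, and 8 without bri1-1D replicate 1 or 3.

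**Figure D4:**
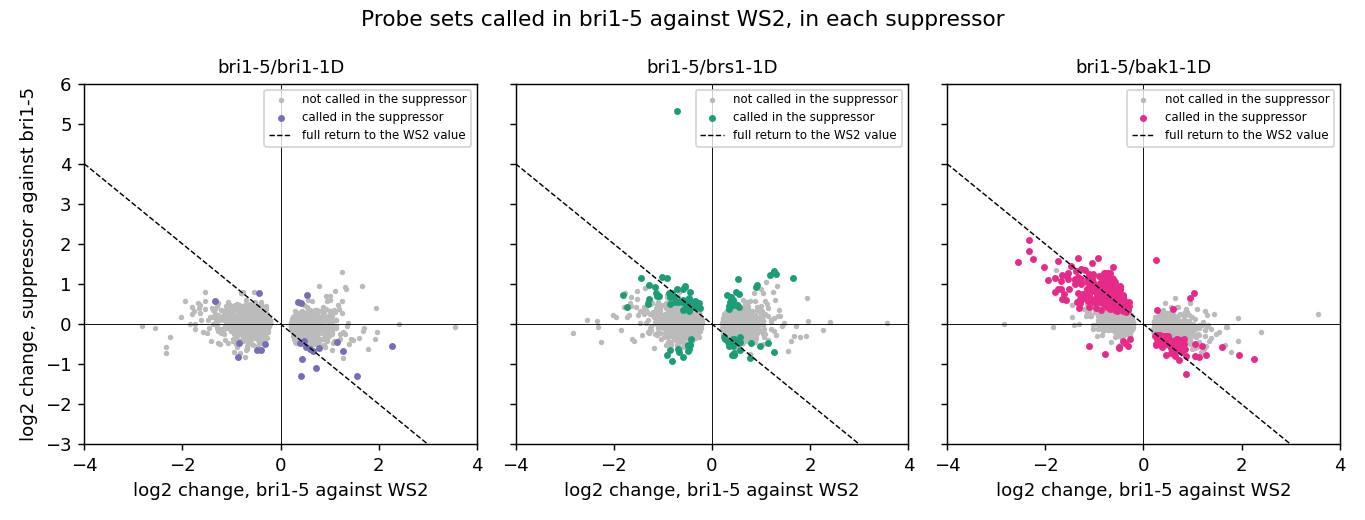
Log2 change of the suppressor against bri1-5 (vertical) on the log2 change of bri1-5 against WS2 (horizontal) for the 2799 probe sets called in bri1-5, 1 point per probe set and 1 panel per suppressor, coloured where called in the suppressor. The dashed line marks a full return to WS2; in bak1-1D 401 coloured points lie in the quadrants of opposite sign.

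Whether the suppressors move genes in common was asked of all pairs. AT5G45060 was higher in bri1-5 than in WS2 (0.47 ± 0.08) and lower than in bri1-5 in brs1-1D (-0.45), bak1-1D (-0.48) and bri1-1D (-0.42), the last with an adjusted p of 0.0618 with the replicate block. The bri1-1D call was lost without any 1 of 14 arrays (adjusted p up to 0.272). The brs1-1D call was lost without bri1-5 replicate 3 or brs1-1D replicate 2 (up to 0.0551). Means were 6.07 in WS2, 6.54 in bri1-5 and 6.06 to 6.12 in the suppressors, so every difference rests on the same 3 bri1-5 arrays. With 247406_at and 267305_at, AT5G45060 made up the 3 probe sets called lower in all 3 suppressors. None was called higher in all 3 by limma, where 81 were higher and 75 lower in all 3 at an unadjusted p under 0.05. The count of 3 fell to 0 without WS2 replicate 1, WS2 replicate 2 or bri1-5 replicate 3, and with quantile normalization or median centring. It fell to 1 without bri1-5 replicate 1 or 2, bri1-1D replicate 1 or 2, bak1-1D replicate 1 or 2, or any of the 3 brs1-1D arrays.

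The pair brs1-1D and bak1-1D had 24 probe sets higher and 11 lower in both, where independent lists give 5.53 and 1.19, and 5 in opposite directions. Their covariance was 0.0139 against a simulated 0.0075 from shared arrays. The pair brs1-1D and bri1-1D had 3 higher and 7 lower (0.13 and 0.15 for independent lists; covariance 0.0132, simulated 0.00751). The pair bak1-1D and bri1-1D had 1 higher, 6 lower and 7 opposite (0.324 and 0.391; covariance 0.00411, simulated 0.00749). Part of these counts may again come from the shared bri1-5 arrays.

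Against WS2, the genes that stayed changed were asked for in each suppressor. AT1G14210 was lower by a similar amount in brs1-1D (-3.05 ± 0.12), bak1-1D (-2.83) and bri1-1D (-2.88), and COR15A was higher (2.58 ± 0.28, 2.08 and 2.34). EXO stayed low in brs1-1D (-2.71) and bri1-1D (-2.57), APL4 in brs1-1D (-1.997) and bak1-1D (-1.91), AT2G39920 in bak1-1D (-1.52) and CML38 in bri1-1D (-1.85). AT5G53710 (2.80 and 2.60) and AT4G28140 (2.58 and 2.55) were among the largest rises in brs1-1D and bri1-1D, and AT1G26800 (1.62) and AT2G07240 (1.61) in bak1-1D. These genes are given where they ranked among the 3 largest changes in a direction, which does not make them particular to a line. APL4 was also lower in bri1-1D (-1.84), and AT2G07240 higher in brs1-1D (1.36) and bri1-1D (1.51). AT5G53710 and AT4G28140 were also higher in bak1-1D (1.14 and 1.58).

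All 5 tested brassinosteroid-induced genes were lower than in WS2 in each suppressor line, also when adjusted over the list alone, with a median of -1.52 in brs1-1D, -0.62 in bak1-1D and -1.36 in bri1-1D (camera adjusted p = 8.22e-10, 2.88e-05 and 2.78e-09). XTH genes fell as a list in brs1-1D, bak1-1D and bri1-1D with 4, 3 and 4 of 6 called lower, on both scales of adjustment, and 1 called higher in bak1-1D when adjusted over the list alone (adjusted p = 1.77e-05, 0.00235 and 3.88e-04). Cold genes rose with 3, 2 and 3 of 4 called and all 4 when adjusted over the list alone (adjusted p = 4.97e-04, 4.62e-04 and 0.00101), with adjusted p = 0.153, 0.137 and 0.18 with an estimated correlation. In bak1-1D the immunity list also rose and the jasmonate list fell (adjusted p = 0.0237 for each, and adjusted p = 0.122 and 0.212 with an estimated correlation), and both calls were lost without bak1-1D replicate 2 (0.054 for each). In brs1-1D 3 of 4 flavonoid genes were called higher, also when adjusted over the list alone, with an adjusted p of 0.0876 for the list (0.0168 without the filter on low values and 0.0479 with a floor). There the jasmonate list had a median of 0.59 and a mean of 0.11 with the camera direction down, and the immunity list a median of -0.07 and a mean of 0.03, and neither was called (adjusted p = 0.916 and 0.986).

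Of the 10 comparisons of 9 lists, camera called 32, and 15 of those held with an estimated correlation. Those were the brassinosteroid-induced list in bri1-5, brs1-1D, bak1-1D and bri1-1D against WS2, in bak1-1D against bri1-5 and in bak1-1D against both other suppressors; the XTH list in the 4 lines against WS2 and in bak1-1D against brs1-1D; and the auxin list in bri1-1D against bri1-5 and in bak1-1D against both other suppressors.

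Called probe sets against WS2 numbered 3241 in brs1-1D (1735 higher, 1506 lower), 1595 in bak1-1D (777 and 818) and 3300 in bri1-1D (1656 and 1644). Which direction held more calls depended on scaling, with 1563 higher and 1739 lower in brs1-1D and 1442 and 1825 in bri1-1D after median centring, and 834 and 731 in bak1-1D after quantile normalization. The bak1-1D count was 828 and 1049 without WS2 replicates 2 and 1, and 900, 970 and 928 without bak1-1D replicates 1, 2 and 3. Of the 2799 probe sets called in bri1-5, 64.7% were no longer called against WS2 in bak1-1D, 36.7% in brs1-1D and 30.3% in bri1-1D. A lost call is not by itself a return to WS2, since bri1-1D lost 847 calls with a recovery of -0.64%. Of the lost calls, 8 of 847 were opposite calls in bri1-1D, 66 of 1026 in brs1-1D and 360 of 1811 in bak1-1D. The 25S rRNA control probe set was called higher in bri1-1D than in WS2, by 1.97 ± 0.28 (7.94 to 8.50 against 6.10 to 6.27, adjusted p = 4.5e-04 over the controls).

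Differences between suppressors were tested directly. EXO was higher in bak1-1D than in brs1-1D by 2.09 ± 0.18 (adjusted p = 9.79e-06) and than in bri1-1D by 1.95 ± 0.18 (adjusted p = 1.23e-05). The brassinosteroid-induced list was higher in bak1-1D than in both (camera adjusted p = 1.94e-08 and 6.02e-06), with 4 and 3 of 5 members called and 5 and 4 when adjusted over the list alone. DFR was higher in brs1-1D than in bri1-1D by 0.99 ± 0.17, a call lost without bri1-1D replicate 3 (adjusted p = 0.0529). Called probe sets numbered 1270 between bak1-1D and brs1-1D, 1611 between bak1-1D and bri1-1D, and 346 between brs1-1D and bri1-1D. The first was 719 and 835 without bak1-1D replicates 2 and 3 and 762 without brs1-1D replicate 2, and the second was 909 and 984 without the same bak1-1D arrays and 1033 without bri1-1D replicate 3. The third was 224 and 81 without bri1-1D replicates 2 and 3, and 161, 210 and 148 without brs1-1D replicates 1, 2 and 3.

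The genes next to the altered loci were examined because the levels of BRI1, BAK1 and BRS1 were not analysed here. In bak1-1D, AT4G33440, 1 gene from BAK1, was higher than in bri1-5 by 0.77 ± 0.11 (adjusted p = 7.73e-04). In brs1-1D, AT4G30620, 1 gene from BRS1, was lower (-1.21 ± 0.14), and AT4G30470, 14 genes away, was higher by 0.47 ± 0.10 (adjusted p = 0.02), a call lost without bri1-5 replicate 1, 2 or 3 or brs1-1D replicate 2 (adjusted p up to 0.0866). In bri1-1D, 0 of 10 neighbours of BRI1 were called by limma, with 3 at an unadjusted p under 0.05. The neighbours cover only genes with a named probe set, because probe sets with no listed gene could not be placed along the chromosomes. Among those, 252891_at (0.92 ± 0.10) and 252890_at (0.92 ± 0.11) were called higher in bri1-1D than in bri1-5. In brs1-1D, 253579_at was called higher than in bri1-5 (5.32 ± 0.08). Whether any of these probe sets lies near BRI1 or BRS1, or measures them, was not tested. The 0 of 10 therefore does not exclude a change near BRI1, and the named neighbours may miss changes near BRS1. Of all 30 neighbours 3 were called where 0.56 would be expected from the calls of each line (exact one-sided p = 0.0172), and with the 2 calls left when AT4G30470 was lost the p was 0.107.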

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

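Tests of the noise in shared bri1-5 arrays, of single arrays behind the recovery, of chance among the called neighbours, alone or clustered, and all tests of the probe sets changed in 4 lines were chosen after the result was seen. The differences below stand out because a direct test between 2 suppressor lines called them.

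Against brs1-1D, bak1-1D had higher EXO (2.09), AT4G28703 (1.68) and AT5G05300 (1.40) and lower AT1G47400 (-1.92), AT1G10585 (-1.75) and AT5G53710 (-1.66), in log2 units with 3 arrays per line. The brassinosteroid-induced (adjusted p = 1.94e-08), XTH (0.00337), auxin (0.00889), photosynthesis (0.0402) and immunity (0.0362) lists were higher in bak1-1D and the jasmonate list lower (0.0335). With an estimated correlation the first 3 were called, and the photosynthesis list was not called after quantile normalization (0.0966) or by fry (0.0977), nor the jasmonate list with a floor (0.122). The photosynthesis call was lost without bak1-1D replicate 2 (0.0686), bak1-1D replicate 3 (0.0791) or brs1-1D replicate 2 (0.264). The immunity call was lost without bak1-1D replicate 1 (0.1) or brs1-1D replicate 1 (0.065), and the jasmonate call without bak1-1D replicate 2 (0.0556) or brs1-1D replicate 3 (0.0845). In all, 1270 probe sets were called between these lines.

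Against bri1-1D, bak1-1D had higher EXO (1.95), AT2G20670 (1.65) and AT3G55840 (1.58) and lower AT5G53710 (-1.45), AT1G07050 (-1.45) and AT4G34950 (-1.42). The brassinosteroid-induced (adjusted p = 6.02e-06), auxin (1.11e-05), photosynthesis (0.00524), immunity (0.00961) and XTH (0.042) lists were higher in bak1-1D, the first 2 also with an estimated correlation. The XTH call was lost without bri1-1D replicate 2 (0.0906) or bak1-1D replicate 2 (0.0867), and with median centring. Called probe sets numbered 1611. Between brs1-1D and bri1-1D, DFR (0.99), AT1G74770 (0.98) and AT1G52050 (0.94) were higher in brs1-1D and AT4G30620 (-1.24), AT3G28320 (-1.22) and AT4G28703 (-1.16) lower, with 346 called probe sets. Without bri1-1D replicate 3 the calls of DFR (adjusted p = 0.0529), AT1G74770 (0.0664), AT3G28320 (0.0529) and AT1G52050 were lost, the last also without bri1-1D replicate 2 or any brs1-1D array (up to 0.0749). The auxin and flavonoid lists were higher in brs1-1D (adjusted p = 0.00899 for each, and 0.0592 for each with an estimated correlation). These calls were lost without bri1-1D replicate 3 (auxin, 0.0903) and brs1-1D replicate 2 (flavonoid, 0.0789), and the auxin call without the filter on low values (0.0637).

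The 25S rRNA control probe set stands out because it lies outside the tested probe sets and still differed between lines. It was higher in bri1-1D than in WS2 (1.97 ± 0.28) and lower than in bri1-1D in bak1-1D (-1.45) and brs1-1D (-1.44). Against bri1-5 it stood 0.91 ± 0.28 higher in bri1-1D without a call (adjusted p = 0.336). The direction of the called differences was the same after quantile normalization and median centring. No cause of this difference was tested.

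The first pattern weighed is the rise in bak1-1D of genes that were low in bri1-5, such as EXO and EXPA8. Noise in the shared bri1-5 arrays that is independent between probe sets is argued against by the covariance of -0.0344, below every simulated value (lowest -0.0086). The simulations held no deviations shared by many genes on an array, so they do not judge such noise. A single array is argued against by the recovery, which was at least 35.3% without any 1 array against at most 8.72% in the other suppressors. WS2 material mixed into the bak1-1D samples would raise all genes by 1 share, but 27 of the 93 probe sets at least 2-fold lower in bri1-5 lay more than 2 SE below the rise that the median share of 54.0% gives. AT1G14210 changed by 0.00 ± 0.12 where 2.103 was expected, and APL4 by -0.06 where 1.26 was expected. A partial return of brassinosteroid-related expression in bak1-1D may explain the pattern, while a difference in growth or handling between the lines stays open.

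The second pattern is that 707 probe sets, AT1G14210, APL4, XTH16 and COR15A among them, differed from WS2 in the same direction in all 4 mutant lines. Simulations of the shared WS2 arrays with no change in any line gave 0 such probe sets, but such data hold almost no calls, so how much shared noise adds stays open. The count was 380 without WS2 replicate 2, so single arrays may decide part of it. Leaving out a WS2 array also lowers the power of all 4 comparisons, and this test cannot tell the 2 apart. A linked chromosome segment that differs between the stocks, as the whole source, is argued against for the 343 genes that could be placed. They held 16 neighbouring pairs, where permutations gave 13.9 on average (permutation p = 0.321). Their share of tested genes ran from 3.61% on chromosome 1 to 5.25% on chromosome 2. Probe sets with no listed gene, and a segment as part of the source, were not tested. The receptor allele that the 4 lines share, unlinked differences between the stocks and a batch of WS2 samples cannot be told apart, because WS2 is the only genotype without the allele.

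The third pattern is the calls next to BAK1 and BRS1, with AT4G33440 higher in bak1-1D (0.77 ± 0.11) and AT4G30620 (-1.21 ± 0.14) and AT4G30470 (0.47 ± 0.10) changed in brs1-1D. Chance stays open: the exact p was 0.0172 for 3 of 30 neighbours, and 0.0223 over windows of consecutive genes, which keep the clustering of calls, but 0.107 and 0.118 for the 2 calls left when AT4G30470 was lost without bri1-5 replicate 1, 2 or 3 or brs1-1D replicate 2. By limma 0 of the 3 were called in the same direction in another suppressor. A difference of bri1-5 from all suppressor lines is argued against for AT4G33440 (-0.01 ± 0.11 in brs1-1D, -0.07 ± 0.11 in bri1-1D). The same holds for AT4G30620 (-0.04 ± 0.14 in bak1-1D, 0.03 ± 0.14 in bri1-1D). For AT4G30470 (0.19 ± 0.10 in bak1-1D, -0.08 ± 0.10 in bri1-1D) the missing calls do not decide. An effect of the dominant alleles on neighbouring genes may explain these calls, and an unrelated change nearby in the same stock was not tested.

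The 6 arrays of 2 genotypes can be split in 10 ways, the real one included, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many calls. Every other split mixes the 2 genotypes, so their difference enters the spread and few calls follow by construction. The counts of other splits therefore do not judge chance. The real and highest other counts were 2799 and 0 for bri1-5 against WS2, and 273 and 0, 690 and 0, and 39 and 3 for brs1-1D, bak1-1D and bri1-1D against bri1-5. Against WS2 they were 3241 and 0, 1595 and 0, and 3300 and 1. Between suppressors they were 1270 and 0, 1611 and 1, and 346 and 0. Opposite calls were 80, 401 and 15 in brs1-1D, bak1-1D and bri1-1D, with 0 as the highest other.

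For the probe sets called in all 3 suppressors, 4 of 100 splits of the 12 arrays, the real one included, gave 3 or more. The highest other split gave 250. The splits mix genotypes that differ, which may by itself give high counts, and the structure behind the 250 was not tested further. Regrouping different genotypes is no test of unchanged lines, so chance is not excluded for the count of 3. For the list calls, 3 of 100 splits of the 15 arrays gave 32 or more, the real one included, and the highest other was 35.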

How the results depend on the processing

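The probe sets changed in all 4 lines, with all their alternatives, were chosen after the result was seen. No call of a named gene or list changed its direction, while the recovery in bri1-1D, near 0, ran from -4.37% to 4.70% without 1 array. Of 193 counts under other settings 134 stayed within 1.5 times the reported count, and of 270 counts without 1 array 219 did. Calls of named genes held in 664 of 690 tests under other settings and in 1544 of 1725 without 1 array. List tests kept their side of the threshold in 497 of 540, with 26 lost and 17 gained, and without 1 array in 1291 of 1350, with 25 lost and 34 gained. No call of AT1G14210, EXO or APL4 against WS2 was among those lost without 1 array.

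Counts below run in the order bri1-5 against WS2; brs1-1D, bak1-1D and bri1-1D against bri1-5; the same 3 against WS2; bak1-1D against brs1-1D and against bri1-1D, and brs1-1D against bri1-1D. Stricter thresholds lower them by construction. With at least 2-fold they were 150, 31, 74, 3, 233, 74, 190, 98, 109 and 14, with 2, 36 and 1 opposite calls in brs1-1D, bak1-1D and bri1-1D, 0 called in all 3 suppressors and 30 in all 4 lines. At an adjusted p under 0.01 they were 1271, 65, 246, 9, 1672, 554, 1544, 518, 619 and 75, with 11, 137 and 4 opposite, 0 in all 3 suppressors and 255 in all 4 lines. With 1 probe set per gene, where fewer were tested, they were 1410, 116, 326, 12, 1650, 771, 1716, 621, 772 and 182, with 28, 186 and 2 opposite, 0 and 338.

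Array weights, which gave bri1-5 replicate 3 a weight of 2.12 and the others 0.671 to 1.28, called 457 in brs1-1D, 1256 in bak1-1D and 61 in bri1-1D against bri1-5 and 196 in brs1-1D against bri1-1D, with 148 opposite in brs1-1D and 699 in bak1-1D. Fits of the 6 arrays compared, with fewer arrays by construction, called 6 in bri1-1D against bri1-5, 1071 in bak1-1D and 136 in brs1-1D against bri1-1D. Quantile normalization and median centring each gave 0 in all 3 suppressors, and the cause was not tested. Camera with an estimated correlation called 15 lists in place of 32. The splits into higher and lower moved by over 10 points with median centring in bri1-5 against WS2 (1152 and 1605) and in bak1-1D against bri1-5 (583 and 157), and the majority also turned in brs1-1D and bri1-1D against WS2.

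With the replicate number as a replicate block, brs1-1D against bri1-5 had 410 calls and 128 opposite calls, and 106 of 115 named calls held. Of the 9 others, 8 are named in the report for brs1-1D and bri1-1D, and TUB1 in bak1-1D had an adjusted p of 0.0528. The cold list in brs1-1D was not called (0.0686). The XTH (0.0292) and immunity (0.04) lists were called in bak1-1D against bri1-5, where 1 of 3 same-number correlations lay above 0.1. The block changed no other list or named call. Of the 15 arrays, 11 correlated best with an array of their own number.

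Without 1 array counts fell or rose. Fewer arrays in a compared genotype lower the power by construction, and no other cause was tested. The count of bri1-5 against WS2 ran from 1761 (without bri1-5 replicate 3) to 2922. Against bri1-5, brs1-1D ran from 112 to 368 (lowest without brs1-1D replicate 2), bak1-1D from 321 to 736 (bak1-1D replicate 2) and bri1-1D from 6 to 47 (bri1-5 replicate 3). Against WS2, brs1-1D ran from 2309 to 3334, bak1-1D from 828 to 1678 (WS2 replicate 2) and bri1-1D from 2246 to 3377. Between suppressors the ranges were 719 to 1366 (bak1-1D replicate 2), 909 to 1650 (bak1-1D replicate 2) and 81 to 418 (bri1-1D replicate 3). Opposite calls ran from 31 to 100 in brs1-1D (brs1-1D replicate 2), 204 to 424 in bak1-1D (bri1-5 replicate 2) and 3 to 16 in bri1-1D (bri1-5 replicate 3). Probe sets called in all 3 suppressors ran from 0 to 3 (0 without WS2 replicate 1 or 2 or bri1-5 replicate 3), those in all 4 lines from 380 (WS2 replicate 2) and 446 (bak1-1D replicate 1) to 689, called neighbours from 2 to 3, called lists from 26 to 35 and called named genes from 85 to 109. The other arrays that moved a count by over 1.5 times are named with it in the report.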

Other observations

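The grouping of UGT and GST genes, the test without called members and the tests of clustering were chosen after the result was seen. In brs1-1D against bri1-5 the glycosyltransferase genes UGT76E12 (1.21), UGT76E11 (1.11 ± 0.22) and UGT74B1 (0.47) and the glutathione transferase genes GSTU25 (1.00), GSTU22 (0.77) and GSTU20 (0.41) were called higher, 6 of 50 tested UGT and GST genes. Of the 50, 42 had a positive change, with a median of 0.14. Genes for the conjugation of small molecules may rise as a group in brs1-1D against bri1-5, which does not show that the rise is particular to brs1-1D. Whether the few called members carry the rise stays open: the 44 others had a median of 0.11 and an unadjusted camera p of 5.59e-06 (0.00144 with an estimated correlation), but the families were picked for their low p on the same arrays. The median of the 50 genes was also positive with quantile normalization (0.13) and median centring (0.15). Adjusted over 30 families with an estimated correlation, neither UGT (38 genes, adjusted p = 0.0657) nor GST (12 genes, 0.144) was called, and UGT78D1, UGT78D2 and UGT79B1 are also members of the flavonoid list.

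The calmodulin-like genes CML38 (-2.02) and CML42 (-0.93) were lower in bri1-5 than in WS2 and higher in bak1-1D than in bri1-5 (1.42 and 0.77), 2 of 5 tested CML genes each time. The family's adjusted p was 0.00569 and 0.0181, and 0.167 and 0.147 with an estimated correlation. In bri1-5 against WS2, SCPL (0.00569), plastid genome (0.00569), tubulin (0.0255) and ribosomal protein (0.039) genes also passed at the preset correlation and did not with an estimated one (0.37, 0.817, 0.395 and 0.514). Genes called in brs1-1D and bak1-1D against bri1-5 lay next to each other among tested genes more often than in permutations, with 7 pairs against 1.84 (adjusted p = 0.009) and 27 against 13.4 (adjusted p = 0.004). The genes called in bri1-5 against WS2 did not (230 pairs against 241).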
